A study of Rattus norvegicus with 6 samples.

How the data were processed

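Small RNA was sequenced from neonatal Wistar rat cardiac fibroblasts and from exosomes purified from their conditioned medium, with 3 libraries per group per the labels. Cells were grown with 10% serum and conditioned for 48 h with 1% serum depleted of exosomes. Library columns were matched to samples by name; 1 exosome column carried no number and was used as an exosome replicate without a number. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

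The authors deposited raw read counts per mature miRNA, whole numbers, and these counts were the input of every main test. A second deposited table held a normalized signal, counts divided by 1 size factor per library, as its values show. Every value in it lay within 0.0435 of a whole number of reads, and these reads came to between 99.3% and 99.8% of the raw counts. The authors' deposited comparison gave a fold change (ratio of mean normalized counts), its log2 value, a p-value and an adjusted p-value, per the file headers. Its log2 values equalled the log2 of the fibroblast over exosome mean normalized count within 8.89e-10 for all 712 finite values. The tools CASAVA 1.8.2, cutadapt 1.2.1 and DESeq and the genome build rn5 are named in the submitters' processing notes; aligner, counting rule and miRNA annotation release are not given in the sources used here. No coordinates are given. Reads of identical or near-identical miRNA copies, such as let-7 or miR-181 members and numbered hairpin copies, cannot be told apart here, and their values are uncertain.

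The normalized table ended in a row named rest, which names no miRNA and was left out of library sizes and tests except where stated. It held 84.4%, 78.7% and 77.2% of the reads of the exosome libraries and 63.1%, 82.4% and 66.0% of fibroblast libraries 1, 2 and 4.

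Total counts were 120224, 113129 and 118994 in exosomes and 6377441, 12508651 and 2439559 in fibroblasts. A count of 0 allows a share of up to 0.00250%, 0.00265% and 0.00252% in the exosome libraries and 4.70e-05%, 2.40e-05% and 0.000123% in the fibroblast libraries (3 counts of the total). These floors and the intervals cover counting error only, since reads after PCR are not independent molecules. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 4.10 to 621). Across miRNAs, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.59 to 0.76 between exosome libraries, 0.91 to 0.95 between fibroblast libraries and 0.36 to 0.64 between groups.

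Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10, minimum total 15), the quasi-likelihood test on group, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter works on CPM: a count of 10 at the median library size equals 7.81 CPM, which fewer reads reach in the shallow exosome libraries. Fibroblast libraries need more than 10 reads for it. A miRNA scarce in fibroblasts could therefore pass through its exosome reads. The filter removed 30 of 728 miRNAs. TMM factors were 1.34, 1.13 and 0.432 for exosomes and 0.968, 1.99 and 0.792 for fibroblasts, and the biological coefficient of variation was 54.3%. Standard errors are the size of the log2 fold change divided by the square root of the F statistic. For miRNAs with 0 counts in all exosome libraries a fold was given as a lower bound against 3 counts over the exosome group (8.81 CPM); 16 of those listed were at 0.

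The lists, fixed before the data were examined together with the tests, the naming rule and the first set of other settings below, were 24: let-7; miR-17-92 and paralogous clusters; miR-29; miR-30; miR-15, miR-16, miR-195 and miR-497; miR-34 and miR-449; miR-181; miR-23/27/24; miR-99, miR-100 and miR-125; fibroblast and mesenchymal; pro-fibrotic and anti-fibrotic in the cardiac literature; Dlk1-Dio3; miR-322 and miR-503; muscle; endothelial; blood; liver and serum; epithelial; neural; vesicle-exported; non-canonical biogenesis; entries numbered 3000 or above; and minor arms. Those with 3 or more tested members, 23, were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry beside it, adjusted over lists. Members were matched by name, both arms included. Arm usage was tested with edgeR's diffSpliceDGE on 248 hairpins with both arms past the filter, of 265 with both listed; the minor arm had the lower mean log2 CPM over all 6 libraries. Shares of counts and numbers of detected miRNAs were compared with exact two-sided permutation tests, whose smallest p is 0.1.

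Named miRNAs were the 8 with the largest change in each direction among those past the threshold with no overlap between groups and a mean CPM of 50 or more, the 6 with the highest mean CPM per group, both arms of miR-21, up to 4 members past the threshold per list (3 by abundance where none passed) and 5 hairpins per direction. Others are said to be chosen after their values were seen.

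The first set of other settings was DESeq2 size factors, total counts, upper-quartile scaling, library sizes without the 5 most abundant miRNAs, no filter, a stricter filter (10 counts in every library of a group and a mean CPM of 10), a block on the sample number, DESeq2 1.42.0, limma-voom, camera with an estimated correlation, limma on log ratios of arms (offset 0.5), the minor arm by fibroblast mean, minor-arm shares without the 3 hairpins with the most minor-arm counts, the 3 most abundant miRNAs, detection at 5 and 10 counts, list shares without the most abundant miRNA, and leaving out each library. The group difference in the fit with the block rested only on the libraries whose sample number occurs in both groups. Chosen after seeing the data were leaving out miR-873-3p or its hairpin, the reads behind the normalized table, library sizes from the rest row, and fibroblast libraries thinned to about 14776 counts without miR-873-3p, run on all miRNAs of the main test.

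The steps were tested on simulated data with the dispersions and depths of these libraries and the mean of each miRNA over all 6 libraries. Before changes were added, each miRNA had the same mean in both groups. For the miRNA comparison as many changes were drawn up as down. The unequal miR-873-3p share of the real groups was therefore not simulated. The rates below do not cover errors of scaling between libraries. For the miRNA comparison (677 tested), 10.2%, 54.2%, 100% and 100% of changes of 2, 4, 16 and 64-fold were recovered, and 3.01% of calls were false. For arm usage (233 hairpins) 8.70%, 43.5%, 88.5% and 100% were recovered, and 6.49% of calls were false. For lists (692 miRNAs), 5 of 5 changed lists and 0 of 95 unchanged lists were called. These were random lists of miRNAs drawn independently, so the 0 of 95 does not cover lists whose members are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.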

Results

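Small RNA sequencing was used to profile microRNAs (miRNAs, short RNAs that repress messenger RNAs) in cardiac fibroblasts of Wistar rats aged 1 to 2 days and in the exosomes these cells released. Exosomes are small membrane vesicles; here they were collected by ultracentrifugation of medium conditioned for 48 h with 1% vesicle-depleted serum. The series held 3 exosome and 3 fibroblast libraries, and 728 mature miRNAs were listed. Total miRNA counts were 120224 in exosome library 1, 113129 in exosome library 2 and 118994 in the exosome library whose column carried no number, called the unnumbered exosome library here. The fibroblast libraries 1, 2 and 4 held 6377441, 12508651 and 2439559 counts. The median miRNA had 8, 7 and 3 counts in the exosome libraries and 318.5, 1509 and 107.5 counts in the fibroblast libraries.

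A single miRNA, miR-873-3p, held 87.4% ± 2.59 (SD, n = 3) of the exosome counts and 1.34% ± 0.994 (SD, n = 3) of the fibroblast counts (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). Its exosome shares were 84.9% (95% Clopper-Pearson interval 84.7 to 85.1), 87.3% (87.1 to 87.5) and 90.1% (89.9 to 90.2). Its raw counts were 102060, 98791 and 107169 in the exosome libraries and 80123, 48963 and 57905 in fibroblast libraries 1, 2 and 4. Without miR-873-3p the exosome libraries held 18164, 14338 and 11825 counts. The edgeR fit gave miR-873-3p a log2 fold change of 6.28 (SE 2.99), which did not pass the test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.10). Without the unnumbered exosome library the adjusted p was 0.0010, and without fibroblast library 2 it was 0.037; over all alternatives run it lay between 1.4e-11 (DESeq2) and 0.16 (edgeR with no filter).

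**Figure D1:**
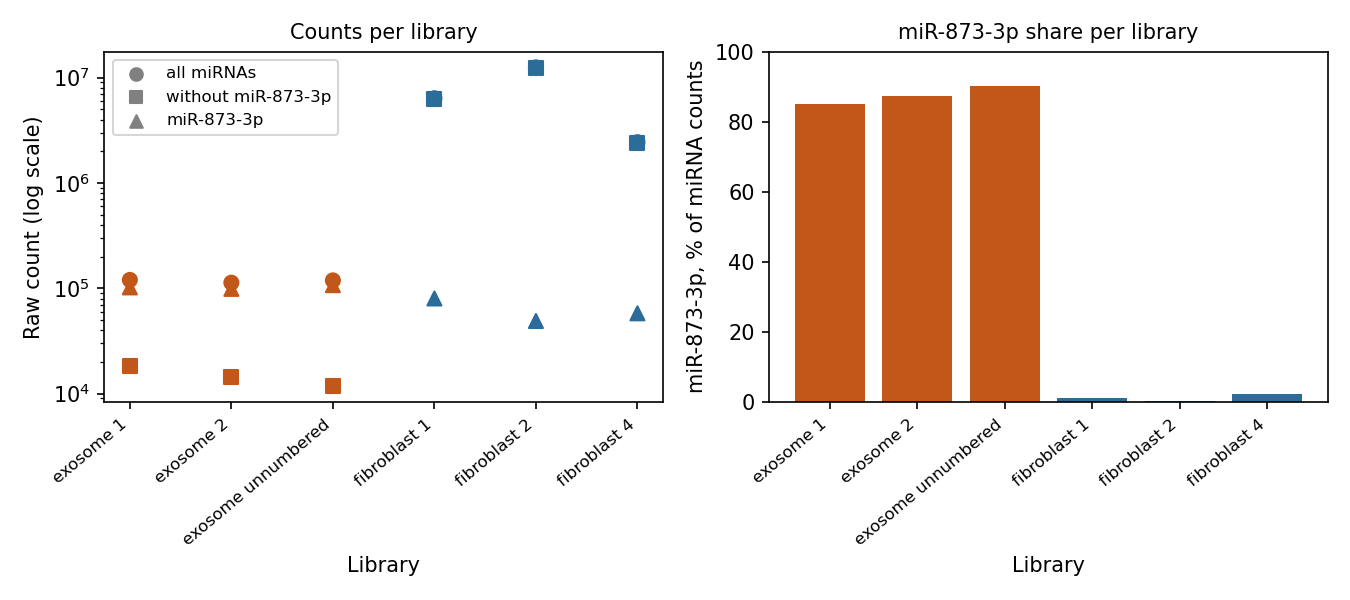
Raw miRNA counts per library on a log scale (left; circles, all miRNAs; squares, without miR-873-3p; triangles, miR-873-3p alone) and the percentage of counts from miR-873-3p (right), with exosome libraries in orange and fibroblast libraries in blue. The miR-873-3p count lay between 48963 and 107169 in the 6 libraries, and its share was 84.9% to 90.1% in exosomes against 0.391% to 2.37% in fibroblasts.

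The first comparison asked which miRNAs differed in relative abundance between exosomes and their parent fibroblasts. The most abundant fibroblast miRNAs were lower in exosomes. miR-143-3p, a miRNA of smooth muscle and mesenchymal cells, made up 25.1% ± 2.30 (SD, n = 3) of fibroblast counts and 0.206% ± 0.293 (SD, n = 3) of exosome counts. miR-22-3p fell from 15.9% ± 1.55 to 0.219% ± 0.243, and miR-21-5p, a miRNA widely studied in cardiac fibrosis, from 8.85% ± 0.899 to 0.118% ± 0.105 (SD, n = 3 each). These exosome shares are lowered by miR-873-3p in the total. Exosome libraries 1, 2 and unnumbered held 18164, 14338 and 11825 counts without it. Of these, 15, 72 and 646 were miR-143-3p, 76, 108 and 594 miR-22-3p and 76, 59 and 285 miR-21-5p, with the most in the unnumbered library. Of the 100 most abundant fibroblast miRNAs, 77 were lower in exosomes, 1 (miR-3560) was higher and 22 were not called.

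In all, 130 of 698 tested miRNAs were lower and 79 were higher in exosomes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An unadjusted p under 0.05 was reached by 263 miRNAs. The exosome and fibroblast values did not overlap for 182 of the 209 called miRNAs. Over all tested miRNAs this held for 39.4%, where chance gives 10%. The median log2 fold change was -3.35 for those lower (-3.33 with the 1 at zero exosome counts set to its floor), 2.38 for those higher and -0.15 for all tested.

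Among the miRNAs with the largest decreases, let-7b-5p of the let-7 family, which is abundant in differentiated cells, was 108-fold lower (log2 fold change -6.76, SE 1.21, edgeR adjusted p = 1.8e-06). It had 2, 1 and 4 exosome counts against 22757, 29297 and 6511 fibroblast counts. miR-28-5p was 53.1-fold lower (log2 -5.73, SE 0.97), miR-31a-5p 43.5-fold (log2 -5.44, SE 1.27), let-7d-5p 37.9-fold (log2 -5.24, SE 1.11), miR-152-3p 36.3-fold (log2 -5.18, SE 0.91) and miR-199a-3p 35.9-fold (log2 -5.17, SE 1.48). Some folds rest on few reads: exosome counts were 2, 0 and 2 for miR-28-5p, 0, 5 and 12 for let-7d-5p and 4, 0 and 2 for miR-152-3p. Of the 130 lower miRNAs, 28 had under 10 counts summed over the exosome libraries, and the median sum was 20.5. miR-143-3p was 53.8-fold lower (log2 -5.75, SE 2.26, edgeR adjusted p = 0.038), miR-21-5p 37.4-fold (log2 -5.23, SE 1.86, 0.020) and miR-22-3p 34.6-fold (log2 -5.11, SE 2.04, 0.041). Of the other abundant fibroblast miRNAs, let-7f-5p was 27.4-fold and miR-26a-5p 23.2-fold lower, while miR-181a-5p, with a log2 fold change of -3.63 (SE 1.52), did not pass (edgeR adjusted p = 0.056). miR-148b-5p had 0 counts in all exosome libraries and 1464 in the fibroblast libraries, and was at least 5.04-fold lower against a floor of 3 counts over the exosome group (edgeR adjusted p = 0.00041).

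The miRNAs higher in exosomes were scarce in fibroblasts, with a median fibroblast abundance rank of 445 against 75.5 for those lower. Exosome depth limited this contrast, since a miRNA scarce in fibroblasts can hardly be called lower against an exosome floor of 8.81 CPM. For example, let-7f-1-3p, with 0 counts in all exosome libraries, was bounded at only 1.74-fold lower or more and was not called. Such miRNAs could also pass the count filter through their exosome reads. miR-93-3p, from the arm opposite miR-93-5p of the cluster that also holds miR-25 and miR-106b, was 51.3-fold higher (log2 5.68, SE 1.30, edgeR adjusted p = 0.00019) and made up 0.615% ± 0.0222 (SD, n = 3) of exosome counts. miR-708-5p was 45.7-fold higher (log2 5.51, SE 1.33) and miR-3552 42.6-fold (log2 5.41, SE 1.34). Ranked by mean CPM (TMM-scaled), these 3 were among the 6 most abundant miRNAs of exosomes with miR-873-3p, miR-3560 and miR-143-3p. The rank of miR-143-3p rested on the unnumbered library, with 646 counts against 15 and 72 in exosome libraries 1 and 2. miR-379-5p was 35.1-fold higher (log2 5.13, SE 0.78), miR-9a-5p, known from neural tissue, 24.1-fold (log2 4.59, SE 0.93), miR-3568 22.8-fold (log2 4.51, SE 0.98) and miR-494-3p 16.3-fold (log2 4.02, SE 0.90). miR-3560 was 7.35-fold higher (log2 2.88, SE 1.07, edgeR adjusted p = 0.027), but was not called without exosome library 2, without the unnumbered exosome library and without fibroblast library 1 or 2 (edgeR adjusted p = 0.11, 0.084, 0.15 and 0.064, and 1.4e-06 to 0.15 over all alternatives). miR-126a-3p, known from endothelium, was 28.8-fold higher by raw counts (log2 4.85, SE 0.85). With the reads behind the deposited normalized table, which held 11, 3 and 5 of its 113, 91 and 98 exosome counts, it was not called (log2 1.17, SE 0.69, edgeR adjusted p = 0.21, and 1.2e-12 to 0.21 over all alternatives). The exosome counts of miR-93-3p, miR-3560, miR-3568, miR-379-5p and miR-126a-3p kept a fixed ratio to those of miR-873-3p, at 7.04, 4.33, 2.15, 0.588 and 0.980 per 1000, where miR-873-3p itself lay between 98791 and 107169, so that a near-constant count gives such a ratio too. The counts that this ratio predicts for miR-93-3p were 72.4%, 18.9% and 75.0% of those found in fibroblast libraries 1, 2 and 4.

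**Figure D2:**
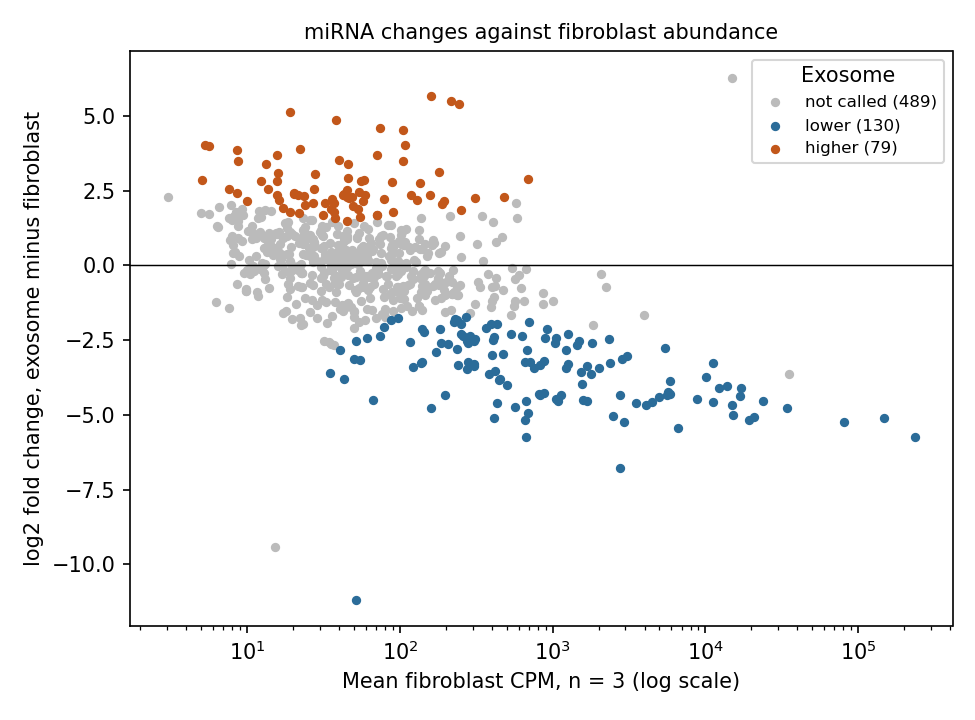
Log2 fold change of exosome over fibroblast (y axis) against mean fibroblast CPM (x axis, log scale, n = 3) for the 698 tested miRNAs; orange, 79 higher; blue, 130 lower; grey, not called. Of the 100 most abundant fibroblast miRNAs 77 were lower; the lowest points, miR-148b-5p and let-7f-1-3p, had 0 exosome counts, so that their fitted position depends on the prior count.

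The split of calls depended on the scaling between libraries, since the fold changes are relative to it. With total counts it was 43 higher and 121 lower, with the 5 most abundant miRNAs left out of the library size 186 and 60, and with library sizes from reads outside the listed miRNAs 33 and 236, and thinning the fibroblast libraries gave 100 and 66. These settings moved the median log2 fold change of all tested miRNAs from -0.15 to -0.57, 1.33, -1.13 and 0.99. Without exosome library 1 or 2 the counts were 54 and 86, or 46 and 88, and edgeR's adjusted p of miR-143-3p became 0.18 and 0.13, of miR-22-3p 0.19 and 0.14, and of miR-21-5p 0.13 and 0.096; their lowest over all alternatives were 2.2e-08, 4.3e-08 and 3.2e-09, with total counts. Of the 69 named miRNAs with a call, 23 and 22 were not called without exosome library 1 and 2, among them let-7f-5p and miR-26a-5p in both and miR-199a-3p in the first.

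The second comparison asked whether miRNA families and tissue-associated groups, listed beforehand, moved together. The list tests did not match members to other miRNAs of equal fibroblast abundance. Along that abundance the median log2 fold change went from -3.24 in the most abundant of 6 groups to 0.91 in the least abundant. Membership in a list was therefore not separated from abundance. Of 28 miRNAs listed as typical of fibroblasts and other mesenchymal cells, 17 were lower in exosomes, 1 (miR-24-1-5p, chosen after its values were seen) was higher and 10 were not called, with a median log2 fold change of -3.40. These miRNAs made up 55.4% ± 0.351 (SD, n = 3) of fibroblast counts and 1.04% ± 0.477 (SD, n = 3) of exosome counts, or 9.05% ± 5.95 of exosome counts without miR-873-3p. Examples were miR-143-3p, miR-31a-5p, miR-21-5p and miR-152-3p. The let-7 family had 9 of 18 members lower and 0 higher, led by let-7b-5p, let-7d-5p, let-7i-5p and let-7f-5p, and held 9.51% ± 0.690 of fibroblast and 0.254% ± 0.139 of exosome counts (SD, n = 3 each).

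By camera with a preset correlation, 6 of 23 tested lists were lower: fibroblast and mesenchymal (adjusted p = 3.7e-07), let-7 (5.7e-05), miR-30 (0.028), miR-23/27/24 (0.028), anti-fibrotic (0.028) and miR-181 (0.046). With an estimated correlation 0 of these calls held, each with an adjusted p = 0.461 with an estimated correlation. Some of the 6 lists share members, so their calls are not separate results. Entries of miR-24 stood in the miR-23/27/24, the fibroblast and mesenchymal and the anti-fibrotic list. Those of miR-27b stood in the miR-23/27/24 and the fibroblast and mesenchymal list, and those of miR-30a and miR-30c in the miR-30 and the anti-fibrotic list. The miR-30 family, abundant in heart, had 7 of 11 members lower, among them miR-30c-5p (log2 -4.33, SE 0.92) and miR-30a-5p (log2 -3.25, SE 1.25). The miR-23/27/24 clusters had 6 of 11 lower, among them miR-24-2-5p (log2 -4.54), miR-23a-3p (log2 -4.46), miR-27b-3p (log2 -4.04) and miR-27a-3p (log2 -3.64), and 2 higher, miR-23a-5p (log2 2.85) and miR-24-1-5p (log2 1.79), named after their values were seen. The miR-181 family had 4 of 10 lower, led by miR-181b-5p (log2 -4.31) and miR-181a-1-3p (log2 -3.22). The list called anti-fibrotic in the cardiac literature had 12 of 33 lower, among them miR-26a-5p (log2 -4.54), miR-29a-3p (log2 -4.52), which represses collagen genes, and miR-30c-5p, and 2 higher, miR-133b-5p (log2 2.44) and miR-24-1-5p.

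Adjusted over the list alone, the members lower were 18 for the fibroblast and mesenchymal list, 12 for let-7, 8 for miR-30, 7 for miR-23/27/24, 6 for miR-181 and 15 for the anti-fibrotic list, and those higher were 2, 0, 0, 2, 0 and 2. The median of the let-7 family was -2.78, or -2.12 with let-7f-1-3p at its floor. Without exosome library 1 and without exosome library 2 only the let-7 and the fibroblast and mesenchymal lists kept their call among the 6. Without fibroblast libraries 1, 2 and 4 in turn the miR-30, miR-181 and miR-23/27/24 lists also lost it (camera adjusted p from 0.075 to 0.16, and the lowest over all alternatives was 0.0061). In these fits the count filter left 402, 359 and 414 miRNAs instead of 698, so that the loss is not that of a library alone. The anti-fibrotic median turned to 0.03 with the fibroblast libraries thinned, where its members still ranked below other miRNAs.

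The Dlk1-Dio3 list, an imprinted miRNA cluster expressed from the maternal chromosome, was the 1 list called higher (camera adjusted p = 0.00016; adjusted p = 0.461 with an estimated correlation). Of its 84 tested members 19 were higher and 5 were lower, the same numbers as adjusted over the list alone. miR-379-5p, miR-299b-5p (log2 4.03, SE 0.72), miR-494-3p and miR-376c-3p (log2 3.86, SE 0.64) led it, although miR-299b-5p and miR-376c-3p had 0 counts in the unnumbered exosome library. The reads behind the normalized table held 2 of the 34 exosome counts of miR-299b-5p, which did not pass the count filter there. Those lower, named after their values were seen, were miR-487b-3p (log2 -3.41), miR-410-5p (log2 -2.79), miR-665 (log2 -2.60), miR-376a-5p (log2 -2.59) and miR-134-3p (log2 -1.74). The median of the list was 0.76; it turned to -0.20 with library sizes from reads outside the listed miRNAs, where the list still ranked above other miRNAs (camera adjusted p = 0.00032, and 0.00012 to 0.00078 over the alternatives with a preset correlation). Its share of counts was 1.72% ± 0.779 in exosomes and 1.48% ± 0.461 in fibroblasts (SD, n = 3; exact permutation p = 0.8), and without miR-873-3p in the total 13.2% ± 3.71 and 1.5% ± 0.474 with no overlap (SD, n = 3; exact permutation p = 0.1).

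**Figure D3:**
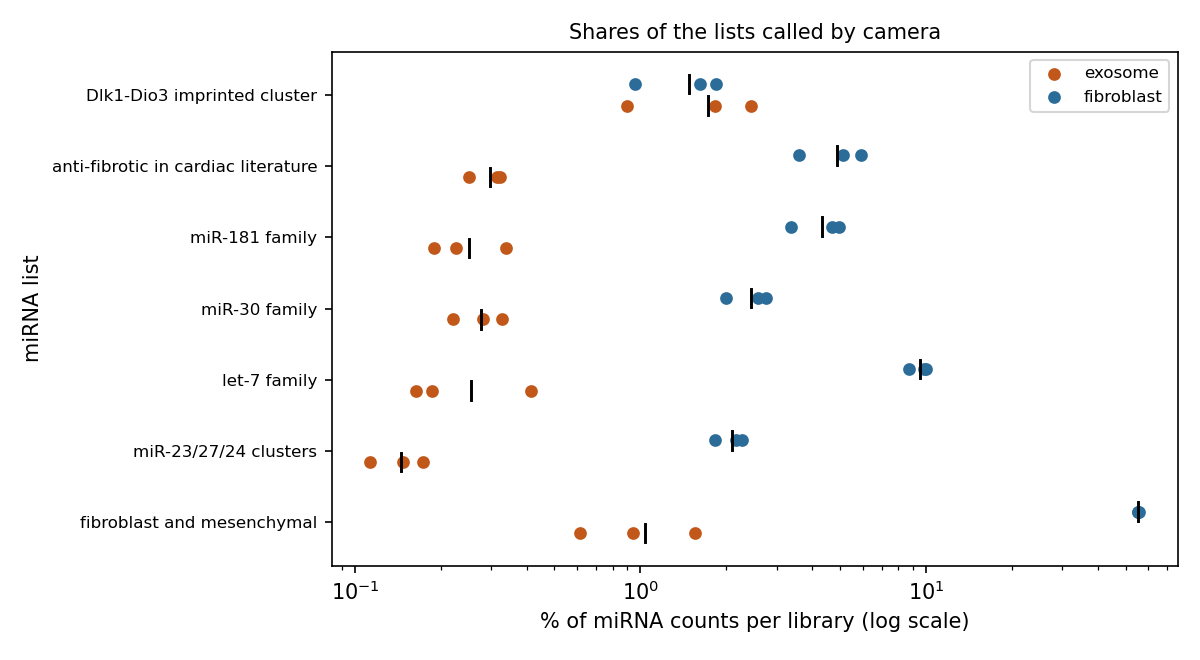
Percentage of miRNA counts per library (x axis, log scale) for the 7 lists called by camera with a preset correlation; points are libraries (orange, exosome; blue, fibroblast) and black bars are group means. The fibroblast and mesenchymal list held 55.4% of fibroblast and 1.04% of exosome counts, while the Dlk1-Dio3 shares of both groups overlapped with miR-873-3p in the total.

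The other family lists and the pro-fibrotic list did not pass by camera with a preset correlation. The list of the miR-99, miR-100 and miR-125 families had 9 of 15 members lower, led by miR-10b-5p (log2 -5.04), miR-125b-5p (log2 -4.58), miR-99b-5p (log2 -4.45) and miR-125b-1-3p (log2 -4.40), and 2 higher, miR-99a-3p and miR-10a-3p (camera adjusted p = 0.075). The family of miR-15, miR-16, miR-195 and miR-497 had 5 of 10 lower, among them miR-322-5p (log2 -4.93) and miR-16-5p (log2 -4.33) (0.080). In the X-linked cluster of miR-322 and miR-503, 5 of 10 were lower, among them miR-322-5p, miR-450a-5p (log2 -4.74) and miR-351-5p (log2 -4.68), while miR-503-5p was higher (log2 2.78, named after its value was seen) (0.080). The list called pro-fibrotic had 7 of 19 lower and 0 higher (0.076), among them miR-21-5p, miR-22-3p and miR-125b-5p. The miR-34 and miR-449 family had 3 of 10 lower, miR-34b-5p (log2 -4.75), miR-34c-5p (log2 -4.61) and miR-34a-5p (log2 -1.80) (0.18), and the miR-29 family 1 of 7, miR-29a-3p (0.31). In the miR-17-92 and paralogous clusters 2 of 27 were higher, miR-93-3p and miR-92b-5p (log2 2.29), and 4 lower, among them miR-25-3p (log2 -2.31) and miR-18a-3p (log2 -2.21) (0.951, with a median of -0.11 where the test pointed higher). Adjusted over the list alone, lower and higher members were 9 and 2, 5 and 0, 5 and 1, 7 and 0, 3 and 0, 1 and 0, and 4 and 1 for these 7 lists in this order. The list of the miR-99, miR-100 and miR-125 families passed with total counts (camera adjusted p = 0.013), the block (0.016), without the unnumbered exosome library (0.031) and under 3 settings chosen later (0.0075 to 0.049), with adjusted p = 0.245 to 0.664 with an estimated correlation in the same fits and adjusted p = 0.461 in the first fit. The pro-fibrotic list passed with total counts (0.033) and without the unnumbered library (0.042), but with an estimated correlation the adjusted p = 0.552 and 0.492 there. Its median turned from -0.71 to 1.27 with the fibroblast libraries thinned. The miR-15, miR-16, miR-195 and miR-497 list passed with the block (0.045), without fibroblast library 1 (0.047) and with thinning (0.047), but with an estimated correlation the adjusted p = 0.664, 0.540 and 0.302 there. In the first fit both lists had adjusted p = 0.461 with an estimated correlation. Passing with the block rested only on the libraries whose sample number occurs in both groups.

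Lists of miRNAs from other cell types held under 1% of the counts in both groups, and those large enough to be tested did not pass by camera. The shares of both groups overlapped for the neural (0.332% ± 0.0648 in exosomes against 0.307% ± 0.13 in fibroblasts), epithelial (0.201% ± 0.0851 against 0.240% ± 0.102), muscle (0.0648% ± 0.0384 against 0.0420% ± 0.0259) and blood lists (0.0541% ± 0.0215 against 0.0530% ± 0.0268; SD, n = 3; exact permutation p = 0.8, 0.7, 0.5 and 0.9). The liver and serum share was lower in exosomes with no overlap, 0.0512% ± 0.0296 against 0.184% ± 0.0270 (SD, n = 3; exact permutation p = 0.1). Without miR-873-3p in the total the shares of all 5 were higher in exosomes with no overlap: neural 2.65% ± 0.121 against 0.310% ± 0.128, epithelial 1.55% ± 0.389 against 0.243% ± 0.101, muscle 0.487% ± 0.231 against 0.0425% ± 0.0258, blood 0.421% ± 0.121 against 0.0536% ± 0.0266, and liver and serum 0.386% ± 0.154 against 0.187% ± 0.0257 (SD, n = 3; exact permutation p = 0.1 each). The 3 endothelial miRNAs listed held 0.0926% ± 0.00752 of exosome and 0.0140% ± 0.00300 of fibroblast counts (SD, n = 3), but 0.0124% ± 0.00616 and 0.0128% ± 0.00318 of the reads behind the normalized table (SD, n = 3; exact permutation p = 0.9), with miR-126a-3p called higher by raw counts only and miR-126a-5p not called (log2 0.30, edgeR adjusted p = 0.78); the list had fewer than 3 tested members and was not tested as a list. Among 10 muscle members miR-208b-5p (log2 2.55) and miR-133b-5p were higher and miR-499-5p (log2 -3.78) lower (camera adjusted p = 0.18). Among 10 blood members miR-451-5p was higher (log2 2.82, SE 0.70) (0.31), among 13 epithelial members miR-141-5p (log2 3.88), miR-200a-5p (log2 2.38) and miR-200b-5p (log2 1.60) (0.14), and among 19 neural members miR-9a-5p, miR-137-5p (log2 1.70) and miR-218a-1-3p (log2 1.69) (0.14). Of 8 liver and serum members 2 were lower, miR-192-5p (log2 -3.30) and miR-215 (log2 -2.44) (0.67). Adjusted over the list alone, the calls of these 5 lists were 2 higher and 1 lower, 1 and 0, 3 and 0, 3 and 0, and 0 and 2.

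Of 12 miRNAs reported as exported in vesicles of other cells, miR-320-5p (log2 3.53, SE 0.69) and miR-451-5p were higher and 10 were not called (camera adjusted p = 0.17); 10 of these 12 also stood in the blood list. Of 12 with non-canonical biogenesis miR-320-5p was higher, and miR-1839-5p (log2 -3.32) and miR-664-3p (log2 -1.77) were lower (0.951). Among 98 entries numbered 3000 or above 17 were higher, led by miR-3552 and miR-3568, and 14 lower, led by miR-3586-3p (log2 -3.78) and miR-6215 (log2 -3.42) (0.080; 0.031 without the unnumbered exosome library and 0.048 without fibroblast library 2). With an estimated correlation these 3 became adjusted p = 0.461, 0.492 and 0.449. Adjusted over the list alone, the numbers higher and lower were 2 and 0, 1 and 2, and 18 and 15. By fry, which tests whether the members move one way on balance, 8 lists passed: let-7, fibroblast and mesenchymal, pro-fibrotic, anti-fibrotic and, with higher members, Dlk1-Dio3, neural, epithelial and muscle. By fry 0 lists passed with no filter, with the block, and without exosome library 1, exosome library 2, the unnumbered exosome library, fibroblast library 1 or fibroblast library 4 (lowest fry adjusted p from 0.052 to 0.19). Without fibroblast library 2, 15 passed, with 6 of the 8 among them. Fewer miRNAs passed the count filter in each fit without a fibroblast library.

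Exact permutation tests of the share of counts per list could not pass, since 0.1 is the smallest p with 3 against 3 libraries. The shares of 15 of 24 lists did not overlap between the groups. Exosome shares were lower in 13 of them, and the endothelial and the miR-17-92 lists (1.11% ± 0.0884 against 0.665% ± 0.0917, SD, n = 3) were higher. The miR-17-92 difference rested on miR-93-3p. That member alone held 0.615% ± 0.0222 of exosome and 0.0163% ± 0.00525 of fibroblast counts (SD, n = 3), a larger gap than that of the list. Without miR-873-3p in the total 19 of 24 did not overlap, 12 higher and 7 lower in exosomes. Of the 13 lower lists 7 then stayed lower, 5 overlapped, such as miR-30 (2.30% ± 0.868 against 2.48% ± 0.395, SD, n = 3), and the liver and serum list was higher.

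The third comparison asked whether the minor arm of a miRNA hairpin, here the arm with the lower mean log2 CPM over all 6 libraries, took a larger part of its counts in exosomes. In the miR-21 hairpin the minor arm miR-21-3p held 58.9% ± 46.3 (SD, n = 3) of the counts in exosomes and 0.730% ± 0.129 in fibroblasts. In the exosome libraries 1, 2 and unnumbered, miR-21-3p had 286, 650 and 18 counts and miR-21-5p 76, 59 and 285, so that the unnumbered library was closest to fibroblasts. As a single miRNA, miR-21-3p had a log2 fold change of 2.08 (SE 0.92) and was not called (edgeR adjusted p = 0.072). The minor arms of miR-23a (miR-23a-5p, 90.3% ± 8.41 against 6.13% ± 3.87), miR-130a (miR-130a-5p, 65.7% ± 39.6 against 1.88% ± 1.57), miR-10a (miR-10a-3p, 19.5% ± 10.3 against 0.146% ± 0.115) and miR-26a (miR-26a-3p, 8.49% ± 7.39 against 0.0540% ± 0.0527) also took a larger part (SD, n = 3 each).

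Of 248 tested hairpins the minor arm took a larger part in exosomes in 52 and a smaller part in 31 (edgeR's quasi-likelihood test of arm usage with Benjamini-Hochberg adjustment). Of the 52, 45 had a major arm called lower, 10 a minor arm called higher and 5 both. The differences in log2 fold change, minor minus major arm, were 7.56 for miR-130a (edgeR adjusted p = 4.1e-09), 7.30 for miR-23a and for miR-21 (2.8e-08 and 2.7e-07), 7.22 for miR-10a and 6.42 for miR-26a. The largest in the other direction were -7.65 for miR-93 (edgeR adjusted p = 2.4e-09), where miR-93-5p, minor over all libraries, made up 74.0% ± 10.7 of fibroblast and 1.45% ± 0.171 of exosome counts (SD, n = 3), -5.99 for miR-376a, -5.45 for miR-376c, -5.35 for miR-708 and -5.30 for miR-365. Those of miR-376c and miR-365 rested on few exosome counts, 51 and 65 over both arms and all exosome libraries, and neither passed with the fibroblast libraries thinned. As for miR-93, the arm called minor was the larger arm in fibroblasts for miR-376a (80.3% ± 9.44), miR-376c (64.5% ± 12.9) and miR-365 (73.0% ± 24.1). For miR-708 it was the smaller arm there (37.9% ± 31.1, SD, n = 3 each). Leaving out fibroblast libraries 1, 2 or 4 reduced the 52 to 20, 20 and 21, as fewer arms passed the count filter, and the 31 became 18, 19 and 21. With the minor arm set by the fibroblast libraries alone, 72 were larger and 11 smaller. Choosing the arm on 1 of the compared groups gives part of such a shift without any change.

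**Figure D4:**
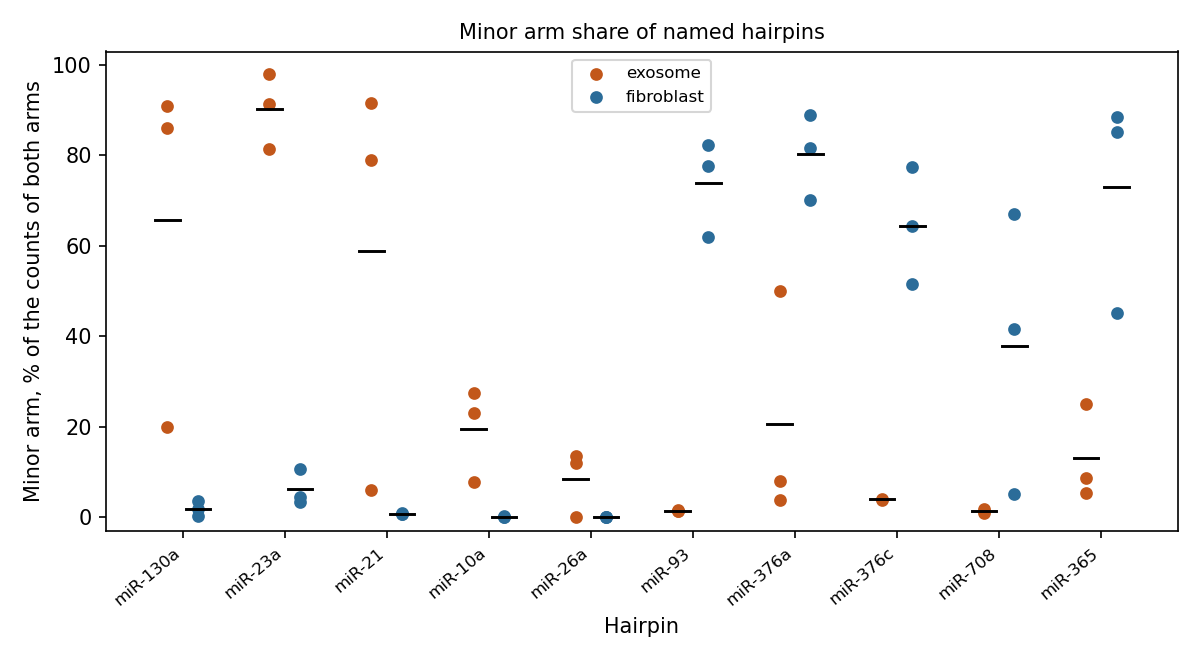
Percentage of the counts of both arms that came from the minor arm (y axis) for the 10 named hairpins; points are libraries with at least 1 count (orange, exosome; blue, fibroblast) and black bars are group means. The minor arm of miR-23a held 90.3% in exosomes and 6.13% in fibroblasts, and the exosome libraries of miR-21 and miR-130a were spread widely.

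The list of all minor arms had 17 of 248 members higher and 26 lower, or 13 and 25 adjusted over the list alone (camera adjusted p = 0.469; the median of -0.05 and mean of -0.23 were negative where the test pointed higher). Among those lower were miR-148b-5p, miR-28-5p, let-7d-5p and miR-152-3p. In fibroblasts let-7d-5p and miR-152-3p were the larger arm of their hairpins (83.9% ± 4.51 and 70.2% ± 4.84, SD, n = 3), while miR-148b-5p and miR-28-5p were the smaller. Over all hairpins with both arms, minor arms held 2.21% ± 1.06 of the paired counts in exosomes and 3.68% ± 0.737 in fibroblasts (SD, n = 3; exact permutation p = 0.1). Without the miR-873 hairpin the order turned, to 23.6% ± 8.27 in exosomes and 3.73% ± 0.702 in fibroblasts (SD, n = 3; exact permutation p = 0.1).

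The complexity of the libraries was compared last. The 10 most abundant miRNAs held 91.5% ± 2.76 of exosome and 67.9% ± 2.04 of fibroblast counts (SD, n = 3; exact permutation p = 0.1). Without miR-873-3p they held 34.7% ± 9.26 and 68.7% ± 2.51, the opposite order. After thinning each library to 113129 counts, 640 ± 59.2 miRNAs were detected in exosomes and 661 ± 52.1 in fibroblasts, a difference within the spread between libraries (SD, n = 3; exact permutation p = 0.7). Without miR-873-3p and at the lower depth of 11825 counts the numbers were 627 ± 45.2 and 410 ± 76.0 (SD, n = 3; exact permutation p = 0.1).

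The authors' deposited table listed 53 miRNAs with an adjusted p under 0.05, all higher in fibroblasts and 0 higher in exosomes, where edgeR called 79 higher (263 at an unadjusted p under 0.05 in either direction) and DESeq2 92. Of the 53 in the authors' deposited table, 52 were also called lower in exosomes by edgeR.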

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

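Of the tests below, those on the splits of the libraries were planned, and all others were chosen after the result was seen; 4 of them were also changed after their first values had been seen, as stated beside each. Outside the miRNA comparisons, the row of the normalized table named rest held 84.4% of the reads in exosome library 1, the highest exosome share (exosomes 80.1% ± 3.76, fibroblasts 70.5% ± 10.4, SD, n = 3, exact permutation p = 0.3). What these reads are was not tested.

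The first pattern is that miR-873-3p held most exosome counts. Its raw counts spanned only 2.19-fold over the 6 libraries, and of 90 pairs of a fibroblast library and 1 of 30 miRNAs in a fixed ratio to it, 0 lay more than 3 Poisson SD under the count that ratio predicts. This decides nothing on about the same number of reads from 1 source in every library, which cannot be told apart from other causes: the prediction reached 0.5 of the count in 5 of the 90 pairs (median 3.15% of the count), so that few could fall below it, and miR-873-3p spanned only 98791 to 107169 in the exosome libraries, where any near-constant count keeps a fixed ratio (the need for predictions near the counts was added after the 0 was seen). A cell transcript taken up by exosomes stays open: the log2 count ratio of fibroblast library 2 over 4 was -0.24 for miR-873-3p against a median of 2.41 for the 100 most abundant miRNAs, yet the lowest of these was -1.16. The source of the reads was not tested.

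The second pattern is that miRNAs called higher in exosomes were scarce in fibroblasts. Reads of the source that gives miR-873-3p would keep a fixed ratio to it. In 17 of 49 testable calls this held (34.7%, 95% Clopper-Pearson interval 21.7 to 49.6), and these 17 stay open. In 23 of 49 that ratio spanned over 3-fold, so that this source alone with counting error does not give those 23. The share itself decides nothing, since its interval treats miRNAs of the same libraries as independent. The ratio test also covers counting error only, which the exosome libraries exceeded (chi-square per degree of freedom 4.10 to 19.5). Background in proportion to the rest reads is not the whole cause, since 32 of 79 calls stayed with library sizes from those reads. The other 47 ended and stay open. The median log2 fold change of the 79 went from 2.38 to 1.44. A median above 1 was the criterion before it was replaced by the number of calls. Low exosome depth, taken as chance highs, is not the whole cause: for the 7 to 102 miRNAs called from 4 libraries, the median log2 ratio in the exosome and fibroblast library left out was 0.98 to 4.04 over 9 pairs, which share libraries (-0.70 to 0.01 for all tested miRNAs), and in each pair it lay 0.435 or more above the highest of 1000 random sets of tested miRNAs of equal size and fibroblast abundance, while its part in single calls stays open (this form replaced a bound of 0.5 of the median in the fit, which 8 of 9 pairs exceeded and the unnumbered exosome library with fibroblast library 4 did not, at 0.40; the first forms thinned the fibroblast libraries, which could not lower the median, and gave 4.11, or 3.22 with 18 miRNAs at the floor, and 4.69 with a count filter). The test on left-out libraries does not cover the exosome floor of 8.81 CPM, against which miRNAs scarce in fibroblasts can hardly be called lower. Export of the miRNAs called higher in exosomes remains an untested hypothesis.

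The third pattern is that the unnumbered exosome library held more of the abundant fibroblast miRNAs: miR-143-3p had 646 counts there against 15 and 72 in exosome libraries 1 and 2. RNA of whole cells in that library cannot be told apart from other causes, since Spearman's rho with the fibroblast mean over the 50 most abundant miRNAs other than miR-873-3p was 0.80 (0.20 and 0.39 in libraries 1 and 2), between the bounds of 0.5 and 0.9 set for the test; its first form included miR-873-3p and gave 0.803. These 50 miRNAs made up 34.2% of its counts without miR-873-3p, against 12.3% and 13.5%. No biological explanation was tested for this library.

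The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. In 1 of 10, the real one, 209 miRNAs were called, and the highest of the others was 0. For hairpins 1 of 10 gave 83, and the highest of the others was 2. Every other split held exosome and fibroblast libraries on both sides, so that the group difference widened the spread within them. Few calls could come from such splits, and their low counts decide nothing.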

How the results depend on the processing

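Leaving out miR-873-3p or its hairpin, the reads behind the normalized table, the rest-row library sizes and thinning were chosen after seeing the data, the others were planned. The count of miRNAs higher in exosomes (79) became 43 with total counts, 186 without the 5 most abundant miRNAs in the library size and 33 with rest-row library sizes; that of lower miRNAs (130) became 60 without those 5, 236 with rest-row library sizes and 66 with thinned fibroblast libraries. These settings change the scaling or the depth by construction. Leaving out 1 library gave 46 to 78 higher (46 without exosome library 2) and 86 to 139 lower (86 without exosome library 1). Without fibroblast libraries 1, 2 and 4 only 402, 359 and 414 miRNAs passed the count filter, against 698 with all libraries. Lists called higher numbered 1 to 2 (2 without the unnumbered exosome library or fibroblast library 2) and lower 2 to 8 (2 without exosome library 1 or 2, 3 without fibroblast library 2 or 4), and 0 and 0 with an estimated correlation. With 1 library left out, hairpins with a larger minor part numbered 20 to 58 and with a smaller part 18 to 33, with 20, 20 and 21 larger and 18, 19 and 21 smaller without fibroblast libraries 1, 2 and 4, where fewer arms were tested. With the minor arm set by fibroblasts, which are 1 of the compared groups, 72 were larger and 11 smaller, and with thinning 36 and 12.

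The minor-arm share difference of -1.47 points became 0.260 with the minor arm set by fibroblasts and 19.9 without the miR-873 hairpin. The difference in the share of the 10 most abundant miRNAs, 23.6 points, became 39.1 for the 3 most abundant and -33.9 without miR-873-3p. The difference in miRNAs detected at equal depth (113129 counts), -21, became -58.3 and -71.7 for detection at 5 and 10 counts, -47.7 to 13.2 with 1 library left out (13.2 without the unnumbered exosome library and 4.33 without fibroblast library 2), and 217 without miR-873-3p at 11825 counts, where depth changed as well.

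Test directions turned for 2 lists that never passed. For the list miR-17-92 and paralogous clusters this was with the block (median -0.53) and without the unnumbered exosome library (median -0.30; -0.38 to 0.095 over libraries left out). For the list non-canonical biogenesis it was with total counts (-1.07), the block (-1.02), thinning (0.63) and each fibroblast library left out (-1.19 to -0.54 over all 6). Elsewhere the cause was not tested. Of the named miRNAs' values under these settings 1176 stayed on their side of the threshold, 26 gained a call, 0 turned direction and the others lost a call; for lists 315 stayed, 27 lost and 13 gained a call and 8 turned, and for hairpins 162 stayed and 2 lost it.

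The sample numbers 1 and 2 are shared by both groups. Deviations of same-numbered libraries from their group means correlated with r = -0.10 and 0.17 across miRNAs. Between exosome library 1 and fibroblast library 2 r was 0.21, and between exosome library 2 and fibroblast library 1 it was -0.03. With so few libraries and exosome counts, these values cannot show whether the numbers pair the samples. With the replicate block 76 miRNAs were higher and 163 lower, 1 list was higher and 8 lower, and 55 and 35 hairpins had a larger and a smaller minor part. Libraries 1 and 2 of each group alone gave the group difference in that fit. The remaining library of each group shared its number with no other library and added nothing to this difference. These calls therefore had little left to measure the spread between libraries. Exosome depth was 11825 to 18164 counts without miR-873-3p, with a median of 3 to 8 per miRNA, and its part in the missed calls was not separated from the spread between libraries. miR-873-3p itself, with 98791 or more exosome counts, had an SE of 2.99, so that counting error was not its limit.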

Other observations

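The grouping by abundance below was chosen after the result was seen, and no explanation was tested. Ranked by fibroblast abundance into 6 groups, the most abundant group had 87 lower and 2 higher in exosomes, with a median log2 fold change of -3.24. The next group had 28 lower and 12 higher (median -0.60), and the following ones 10 and 13 (-0.02), 4 and 22 (0.15), 1 and 15 (0.46) and 0 and 15 (0.91), by edgeR's quasi-likelihood test. Fibroblast libraries differed along the same groups: the median log2 count ratio of fibroblast library 2 over 4 went from 2.41 in the most abundant to 4.86 in the least abundant group, and that of 2 over 1 from 0.95 to 2.59, so that the gradient is not shown to be particular to exosomes. Ranking on 1 of the compared groups gives part of such a gradient without any change, since chance highs in fibroblasts lower the ratio.

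In the X-linked cluster of miR-322 and miR-503, neighbouring miRNAs went opposite ways. miR-503-5p was higher (log2 2.78, edgeR adjusted p = 0.00078), with 174 counts over the exosome libraries, while miR-322-5p (log2 -4.93), miR-450a-5p (log2 -4.74) and miR-351-5p (log2 -4.68) were lower. miR-503-5p was chosen after its values were seen, and it was also 1 of the 30 miRNAs in a fixed ratio to miR-873-3p over the exosome libraries.

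For miR-126a-3p, chosen after its values were seen, the 2 deposited tables differed by a number of reads that followed miR-873-3p. The raw counts exceeded the reads behind the normalized table by 102, 88 and 93 in exosome libraries 1, 2 and unnumbered and by 76, 43 and 59 in fibroblast libraries 1, 2 and 4. This was 0.868 to 1.02 reads per 1000 miR-873-3p counts in the 6 libraries (chi-square p of a fixed ratio 0.876, which covers counting error only). Among the 9 miRNAs with a mean difference of 10 or more reads per exosome library, this ratio spanned 1.17-fold for miR-126a-3p and 1.99-fold for miR-207, and 21.9-fold or more for the other 7, of which some were at 0 in a library. No explanation was tested.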
